A study of Aplysia californica with 33 samples.

How the data were processed

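RNA of single R2 and LPL1 neurons, whole abdominal ganglia and pooled CNS of Aplysia californica was measured on custom 2-colour Agilent arrays. Per the labels' protocols, cRNA was made with 1 round of linear amplification. On reference arrays the neuron carried Cy3 and the CNS Cy5. On direct R2 arrays old R2 carried Cy3 and young R2 Cy5, and on abdominal arrays young tissue carried Cy3 and old tissue Cy5. No dyes were swapped. Scanner software, background correction and normalization within arrays are not given in the sources used here.

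The deposited array values are log10 ratios, centred near 0 on each array by the authors. Scale and direction of the reference arrays were settled from the authors' tables. Across shared names, the slope through 0 of the authors' natural log estimates on the same contrasts of array values was 1.94 to 2.17 for 9 of 10 contrasts, where log10 values read in natural log would give 2.30, with r from 0.849 to 0.929. The remaining contrast, young LPL1 against young R2, had only 5 shared names. The sign showed neuron over CNS. The direction of direct and abdominal arrays is not stated. It was taken as Cy3 over Cy5, as on the reference arrays, and is called likely, so old minus young in the abdominal ganglion is the negative of the deposited value. How the values were centred stays unknown. Values at exactly 2 or -2 in log10 units, with none beyond, show a limit on all 3 DAA old R2 arrays, 1 AAA old R2 array and direct R2 replicate 1 of both platforms. The other arrays hold values beyond 2, or none that reach it, where a limit would not show.

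All values were multiplied by 3.32 to give log2 ratios from the deposited log10 ratios. On AAA the array medians spanned 0.113 log2, over the preset 0.1, so each array was centred on its median. On DAA they spanned 0.0565 and the values were used as deposited. A feature was tested with at least 2 values in every group. Of 44288 DAA features, 2254 had a value only on direct R2 replicate 3 and were not tested, which left 42034. No value column of the series was left unused.

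Groups came from the sample titles. Each reference platform was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 12 arrays, whose 4 groups share 1 estimate of spread. Contrasts were old minus young in R2 and in LPL1, their difference (the interaction), R2 minus LPL1 at each age, and the mean of the 4 groups against 0 for neurons over CNS. Direct R2 and abdominal arrays were tested as 3 arrays against 0. P-values were adjusted by Benjamini and Hochberg over all features of a platform and called under 0.05. With 3 against 3 arrays no exact permutation test can go below 0.1, so the tests rest on limma's pooled spread. Fits were checked on simulated data with 100 changed features per size of change. Of 2-fold and 4-fold changes on AAA, 97% and 100% were recovered for neurons over CNS, 20% and 64% in the abdominal ganglion, and 23% and 82% between old neurons.

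The labels of the reference arrays call the replicates biological. Those of the direct R2 and abdominal arrays give only a replicate number, so whether these are biological replicates is not stated. The authors' deposited table gives the same 3 weights for old R2 and old LPL1 cells, and lists each young sample with 3 animals' weight range, so young samples are likely pools and old samples single animals. P-values measure only the spread between these samples. Replicate numbers were tested as pairs by correlating deviations from the group means. For old R2 and old LPL1 the same-numbered arrays gave r = 0.331, 0.148 and 0.384 on AAA and 0.234, 0.259 and 0.145 on DAA. The numbers therefore likely pair the old cells, in step with the shared weights. The weights are listed without replicate numbers, so the pairing is not settled. The other groups share only a number. The covariance that this pairing alone gives to the age differences of R2 and LPL1 was estimated from the same deviations, and the correlation with no change from it and the spread within groups.

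The authors' contrast tables hold natural log estimates, fold (ratio) values and p-values of a multivariate analysis of variance with factors cell, age and their product, per the authors' methods text, trimmed to over 2-fold and a p-value under 0.05 with no correction named. In all 24351 deposited lines the fold is the exponential of the absolute natural log estimate, and the lowest fold is 2.00. These tables name contigs, with no map to features. Their combined lists, and the authors' RefSeq table, were not used here. The authors' SAM tables hold log2 numerators at a 5% false discovery rate and 2-fold. The methods text and title lines tie them to the direct R2 arrays and the accompanying notes to the abdominal arrays. Their numerators were not recovered from the arrays (R2 of 0.278 on all 18 AAA arrays), so only their feature numbers and names were used, with the authors' deposited signs set against those here. Amounts of RNA in ng, from a supplementary table of the authors, describe the samples.

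Names came from the hit definitions of the 3857 SAM features, linked by feature number. Pairs of features with a shared hit (1032) correlated at r = 0.852 to 0.921 across pairs on each array, as a check of the link. A name was used if descriptive and with an E-value of at most 0.0001, which left 808 features with 361 names. This limit on E was set after the files were seen. Hits are to other species in many cases, and several features can share a name.

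Text names features by this rule: among called features with a usable name whose groups do not overlap (or whose 3 direct arrays share a sign), the 6 largest rises and 6 largest falls, 1 feature per name, and of each gene list the 2 largest called rises and falls. Where no named feature was called, the 5 with the smallest p-value are given. Unnamed features are given at most 2 per direction. The lists were cholinergic transmission, acetylcholine receptors, other transmitter receptors, neuropeptides and prohormones, ion channels, synaptic vesicle and release, mitochondrial respiration, antioxidant defence, chaperones and heat shock, ubiquitin and proteasome, autophagy and lysosome, ribosomal proteins, translation factors, RNA processing, histones and chromatin, DNA repair and telomere, apoptosis, tubulin and microtubule, actin, growth factor, insulin and TOR signalling, cAMP, calcium and plasticity signalling, neurodegeneration-associated proteins, glycolysis and citric acid cycle, vesicle traffic and secretion, and markers of glia and sheath, muscle, haemocytes and other transmitter phenotypes, each matched by words in the name. Lists of at least 5 features were tested with camera (preset correlation 0.01, adjusted over 140 tests), beside camera with an estimated correlation and fry, which asks whether a set moves on balance one way. Camera set each list against the other named features only, most of which the authors selected as higher in young. Higher and lower by camera are therefore relative to those features, not to the whole array or to 0. Groups, tests, naming rule, the words of each list and the settings were fixed before the data were examined, apart from the limit on E, which decides which features are named and enter the lists, and the alternatives said to be added.

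Alternatives were values as deposited or median-centred, quantile normalization, complete features only, eBayes with trend and robust options, array weights, a plain test with each feature's own spread, a 2-fold minimum, each array left out in turn, replicate number as a block, and only the groups compared in the fit. A filter on dim probes was not run, since the values hold no intensities. Other software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.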

Results

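The data set holds 33 2-colour oligonucleotide arrays of the sea hare Aplysia californica, made to ask whether identified nerve cells age differently. R2, in the abdominal ganglion, and LPL1, in the left pleural ganglion, are giant cholinergic neurons that can be recognised from animal to animal and taken out singly. The reference design set neurons of each kind and age against pooled RNA of the central nervous system (CNS), with 4 groups (young LPL1, young R2, old LPL1 and old R2) of 3 arrays each. This was done on both an annotated array (AAA, 41991 features, 18 arrays) and a discovery array (DAA, 44288 features, 15 arrays). Direct arrays hybridised old R2 with young R2 (3 arrays per platform), and 3 further AAA arrays hybridised whole young with whole old abdominal ganglia. In the authors' deposited tables the age given for the CNS is middle. Per the labels young animals weighed 25 to 30 g and old animals 1000 to 14000 g. Against that upper value, the authors' deposited table gives weights of 1001, 1317 and 1447 g for both the old R2 and the old LPL1 cells, and for each young sample lists 25 to 30 g times 3. In that table the extracted RNA was 1545 ± 388 ng in old R2, 385 ± 37.7 ng in young R2, 1577 ± 120 ng in old LPL1 and 350 ± 129 ng in young LPL1 (mean ± SD, n = 3 samples each).

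The values are ratios without the underlying intensities, so no spot's brightness is known. Array medians lay between -0.0332 and 0.0797 log2 on AAA and between 0 and 0.0565 log2 on DAA. Across features, reference arrays of one group correlated at r of at least 0.656 on AAA and 0.392 on DAA. Old R2 arrays correlated with the other groups at 0.407 to 0.865 and 0.308 to 0.672, and their median SD between replicates, 0.33 log2 on both platforms, was the largest of the 4 groups (0.17 to 0.23 on AAA). Gene names were taken from the authors' deposited SAM tables, whose features the authors selected for a difference between old and young, in R2 per their methods text and in abdominal ganglia per the accompanying notes. The counts by gene list below are therefore not independent evidence of a direction of age changes. DAA features carry no name here.

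The first comparison asked which transcripts differ between old and young R2. In old R2 the transcript of an inhibitor of apoptosis protein, a family that binds caspases, rose by 2.20 ± 0.28 log2 (SE; 3 against 3 arrays; limma adjusted p = 0.00171), and Sym32, a putative cell adhesion protein, rose by 2.53 ± 0.37 (adjusted p = 0.00354). Nitric oxide synthase, the enzyme that makes the messenger nitric oxide, fell by 2.36 ± 0.25 (adjusted p = 0.000809), from 1.47 ± 0.31 in young to -0.89 ± 0.43 log2(neuron/CNS) in old R2 (SD, n = 3). SPTR prohormone, a peptide precursor, fell by 3.14 ± 0.46 (adjusted p = 0.00334). Rfc3, a subunit of the replication factor C clamp loader, fell by 3.10 ± 0.54 (adjusted p = 0.00735). A hyperpolarization-activated ion channel rose by 1.86 ± 0.16 (feature 11292, adjusted p = 0.000341). By the rule for naming features, the 3 old arrays of each lay on one side of the 3 young arrays, so this is no added support.

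On AAA, 5571 of 41991 features (13.3%) passed in R2, 2611 higher and 2960 lower in old cells, and on DAA 6015 of 42034 passed, 2817 higher and 3198 lower. All 3 DAA old R2 arrays, and no other DAA reference array, carry the limit at 2 (log10). Only 0, 2 and 0 values stood at 2, and 3, 1 and 1 at -2, on old R2 replicates 1, 2 and 3. So few limited values cannot themselves make these counts. The limit may mark another processing of these arrays. DAA comparisons with old R2, here and below, cannot be told apart from such a processing. Which direction holds more features depends on scaling, on the arrays kept and on the fold demanded. On DAA 1700 were higher and 1460 lower at 2-fold or more, and 4364 and 3804 without old R2 replicate 2. Without young R2 replicates 1 and 2 in turn, 800 and 1504 AAA features were higher and 774 and 1427 lower. On AAA 2905 were higher and 2597 lower with values as deposited, and 2648 and 2364 with quantile normalization, and on DAA 2999 and 2950 with each array centred. Groups did not overlap for 36.2% of all AAA and 35.2% of all DAA features, where chance gives 10%. With 1 array left out the AAA count was 1574, 2931 and 2392 without young R2 replicates 1, 2 and 3, and 3266 without old R2 replicate 2. The DAA count was 2996, 2858 and 2951 without the 3 young R2 replicates in turn, and 3601 without old R2 replicate 3.

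Further large rises were the PRQFVamide precursor, encoding molluscan peptides (2.64 ± 0.77, adjusted p = 0.0455), a protein with PDZ and RING finger domains (2.13 ± 0.62, 0.0445) and an extensin-like protein (1.89 ± 0.46, 0.0243). Further large falls were WW domain-binding protein 4 (-2.48 ± 0.52, 0.0147), a protein interacting with synovial sarcoma X breakpoint 2 (-2.34 ± 0.46, 0.0115) and a further neuropeptide precursor (-2.29 ± 0.45, 0.0119). The PRQFVamide call held only when old LPL1 replicate 2 or old R2 replicate 1 was the array left out, over a range of 1.76 to 3.40 log2. The PDZ and RING call held only without old LPL1 replicate 2, old R2 replicate 1 or old R2 replicate 3 (1.42 to 2.58). The extensin-like call was lost without any 1 of the young R2 arrays or old R2 replicate 2 (1.45 to 2.22), and the WW domain call without young R2 replicate 1 (-2.81 to -2.05).

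**Figure D1:**
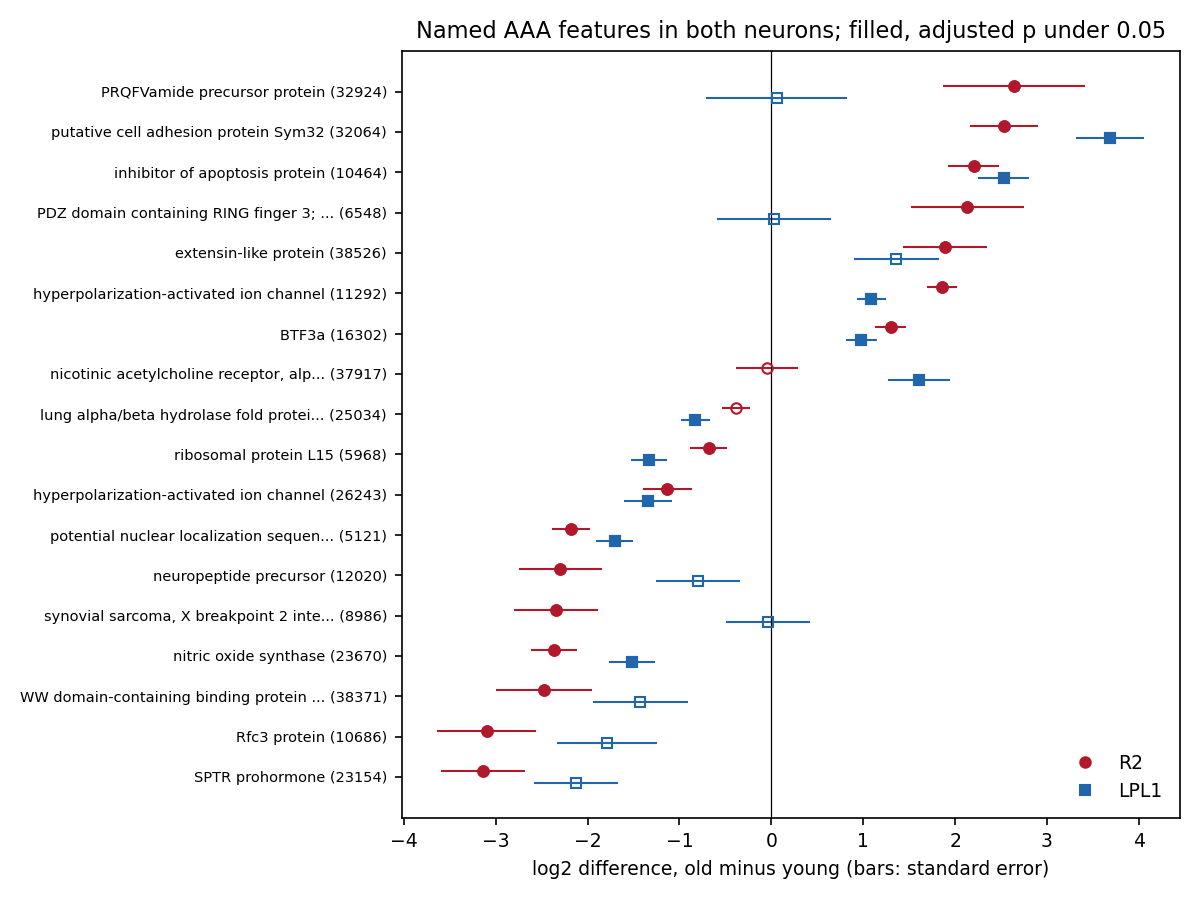
Old minus young log2 difference (horizontal axis) of 18 named AAA features in R2 (red circles) and LPL1 (blue squares), with standard error bars from limma (3 against 3 arrays) and filled symbols where the adjusted p is under 0.05. Sym32 (2.53 in R2, 3.69 in LPL1) and the inhibitor of apoptosis protein (2.20 and 2.53) lie right of 0 in both neurons, and nitric oxide synthase (-2.36 and -1.52) lies left of 0 in both.

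Of the 808 named features, 31 rose, 94 fell and 683 did not pass in R2. Only 103 of the 808 come from the authors' SAM table of features higher in old, and the rest from that of features higher in young. An excess of falls in the lists below may follow that selection. Among transmitter receptors other than those for acetylcholine (22 features), 1 rose and 5 fell (8 adjusted over the list alone). The riser was a glycine receptor alpha subunit (1.36 ± 0.16, adjusted p = 0.00123). All 4 features of GluR5, an ionotropic glutamate receptor subunit, fell, by -2.20 to -1.82 log2, and a GABA A receptor alpha subunit fell by 1.43 ± 0.35 (0.0242). None of 11 features of acetylcholine receptors passed (0 adjusted over the list alone), and the cholinergic transmission list had 0 features with a usable name. Of 89 neuropeptide and prohormone features 2 rose and 14 fell (18 adjusted over the list alone), with a list median of -0.55 log2. Of 21 ion channel features 3 rose and 5 fell (10 adjusted over the list alone). The risers carry a hyperpolarization-activated channel name by an Apis mellifera hit. Feature 29987, of the same channel name by a Panulirus argus hit, fell (-1.30 ± 0.21, 0.00571), and a voltage-dependent calcium channel alpha 1F subunit fell by 1.12 ± 0.28 (0.0283).

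In the tubulin and microtubule list (32 features) 0 rose and 6 fell (13 adjusted over the list alone), with a median of -0.84 log2. Beta-tubulins fell by 2.10 ± 0.38 (feature 30346, adjusted p = 0.00878) and 1.92 ± 0.44 (feature 30786, 0.0206). The synaptic vesicle list (27 features, 0 rose, 3 fell, 5 adjusted over the list alone) holds that second beta-tubulin through its hit name, beside a synaptotagmin XIV-related protein that fell by 1.02 ± 0.27 (0.0325). In glycolysis and the citric acid cycle (23 features) 0 rose and 5 fell (7 adjusted over the list alone), among them fructose-bisphosphate aldolase (-1.09 ± 0.29, 0.0334) and a phosphoglyceride transfer protein (-1.15 ± 0.34, 0.0454), a lipid carrier rather than a glycolytic enzyme. In cAMP, calcium and plasticity signalling (22 features) nitric oxide synthase and monoglyceride lipase (-1.31 ± 0.23, 0.00713), an enzyme of lipid breakdown, fell (2 adjusted over the list alone).

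In the growth factor and insulin list (11 features, 5 adjusted over the list alone) 2 features rose and 1 fell. EPS15R, related to an endocytic substrate of the epidermal growth factor receptor, rose by 1.68 ± 0.22 (adjusted p = 0.00198), and insulin-like peptide precursor II fell by 1.60 ± 0.26 (0.00518). The 2 risers among 4 apoptosis features (2 adjusted over the list alone) were both the inhibitor of apoptosis protein. Both histone and chromatin features (2 adjusted over the list alone) carry the name of the HPA2 acetyltransferase family and fell, one by 1.64 ± 0.36 (0.0168). Ribosomal protein L15 fell by 0.68 ± 0.20 (0.0452), the 1 call of 6 ribosomal features (1 adjusted over the list alone). Of 29 features under translation factors 1 rose and 1 fell (2 adjusted over the list alone). The riser was TFIID subunit 1, a transcription rather than a translation factor (0.78 ± 0.18, 0.0212), and threonyl tRNA synthetase fell by 0.91 ± 0.20 (0.0173). Among markers of other cells, 2 of 6 glia and sheath features fell (2 adjusted over the list alone), with intermediate filament protein A at -1.21 ± 0.18 (0.0034), and 2 of 7 haemocyte features fell (4 adjusted over the list alone), with a galactoside-binding lectin at -1.10 ± 0.28 (0.0284).

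No member passed over all features in mitochondrial respiration (4 features, 4 adjusted over the list alone), antioxidant defence (10, 0), chaperones and heat shock (17, 0), ubiquitin and proteasome (6, 0), autophagy and lysosome (3, 0), RNA processing (2, 0), DNA repair and telomere (4, 2), actin (7, 0), neurodegeneration-associated proteins (8, 0), vesicle traffic (16, 0), muscle (3, 0) or other transmitter phenotypes (6, 0), where the second number of each pair is the count adjusted over the list alone. By camera no list passed in R2. With quantile normalization the R2 list medians changed sign for ribosomal proteins (-0.15 to 0.25 log2), translation factors (-0.21 to 0.14), growth factor signalling (-0.68 to 0.01), vesicle traffic (-0.04 to 0.39) and other transmitter phenotypes (-0.28 to 0.33). Median and mean differed in sign for other transmitter receptors (0.08 and -0.30) and ubiquitin (0.06 and -0.03).

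The same question was asked of LPL1. Sym32 rose by 3.69 ± 0.37 log2 in old LPL1 (SE; 3 against 3 arrays; adjusted p = 0.00261), from -2.98 ± 0.43 to 0.70 ± 0.34 log2(neuron/CNS) (SD, n = 3), and the inhibitor of apoptosis protein rose by 2.53 ± 0.28 (0.00378). A hyperpolarization-activated channel feature rose by 1.09 ± 0.16 (11292, 0.0118), and BTF3a, a basal transcription factor, rose by 0.98 ± 0.17 (0.0231). A nicotinic acetylcholine receptor alpha2 subunit feature rose by 1.61 ± 0.33 (37917, 0.0478), while the other 3 features of that name did not pass. A protein resembling the nucleolar protein Nsr1p fell by 1.71 ± 0.20 (0.00488), nitric oxide synthase by 1.52 ± 0.25 (0.0194) and ribosomal protein L15 by 1.33 ± 0.20 (0.0122). A hyperpolarization-activated channel feature named by a Panulirus argus hit fell by 1.34 ± 0.26 (26243, 0.0383), and a lung alpha/beta hydrolase fold protein by 0.83 ± 0.15 (0.0313). By the rule for naming features, the 3 old arrays lay on one side of the 3 young arrays in each case.

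Sym32, the inhibitor of apoptosis protein and the Nsr1p-like protein passed whichever array was left out. The nicotinic alpha2 call was lost without any 1 of the LPL1 arrays or of the young R2 arrays (1.49 to 1.82 log2). That of channel feature 26243 was lost without any 1 LPL1 array or young R2 replicate 2 or 3 (-1.50 to -1.22), and that of the hydrolase without any 1 young R2 or old LPL1 array or young LPL1 replicate 1 or 3 (-0.91 to -0.67). BTF3a was lost without young LPL1 replicate 1 or 3 or old LPL1 replicate 2 or 3 (0.90 to 1.10), and nitric oxide synthase without young LPL1 replicate 3 or old LPL1 replicate 2 or 3 (-1.66 to -1.37). Channel feature 11292 (1.00 to 1.16) and L15 (-1.49 to -1.12) were lost without young LPL1 replicate 3 or old LPL1 replicate 2.

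On AAA 501 features passed in LPL1, 266 higher and 235 lower in old cells, and on DAA 478 passed, 233 higher and 245 lower (251 and 220 with quantile normalization). The balance turned to 401 higher and 597 lower on AAA without old R2 replicate 3, and to 349 and 182 on DAA without young LPL1 replicate 2. With array weights 3128 and 2251 passed, and with the replicate block 249 and 153. Groups did not overlap for 23.8% of AAA and 20.9% of DAA features (chance 10%). The AAA count was 208 and 82 without young LPL1 replicates 1 and 3, 311 without young R2 replicate 2, 266, 104 and 114 without old LPL1 replicates 1, 2 and 3, and 775 and 998 without old R2 replicates 2 and 3. The DAA count was 130 and 71 without young LPL1 replicates 1 and 3, 280, 186 and 259 without young R2 replicates 1, 2 and 3, 192, 86 and 137 without old LPL1 replicates 1, 2 and 3, and 1283 without old R2 replicate 2. In simulations of 41991 features, with 100 changed per size, the AAA test recovered 27% of 2-fold and 83% of 4-fold changes in LPL1. In R2 the shares were 25% and 83%. The simulated spread was the same in all groups, so these like shares do not show like power in both neurons.

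Of the 808 named features 7 rose and 9 fell in LPL1. By list these were 1 riser of 11 acetylcholine receptor features (1 adjusted over the list alone), 2 risers and 3 fallers of 21 ion channel features (6 adjusted over the list alone), 2 risers of 4 apoptosis features, both the inhibitor of apoptosis protein (4 adjusted over the list alone), 1 faller of 6 ribosomal features (1 adjusted over the list alone) and nitric oxide synthase among 22 features of plasticity signalling (1 adjusted over the list alone). None of 89 neuropeptide features passed (0 adjusted over the list alone). None of the others passed over all features, and adjusted over the list alone 2 features each passed in mitochondrial respiration, antioxidant defence, autophagy, vesicle traffic and the glia and sheath list. By camera with a preset correlation, ribosomal proteins were lower in old LPL1 (median -0.73 log2, adjusted p = 0.00171) and the tubulin list higher (0.61, adjusted p = 0.00786; 0 of 32 features passed singly). Both are relative to the other named features, and neither held by camera with an estimated correlation (adjusted p = 0.995 for both).

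**Figure D2:**
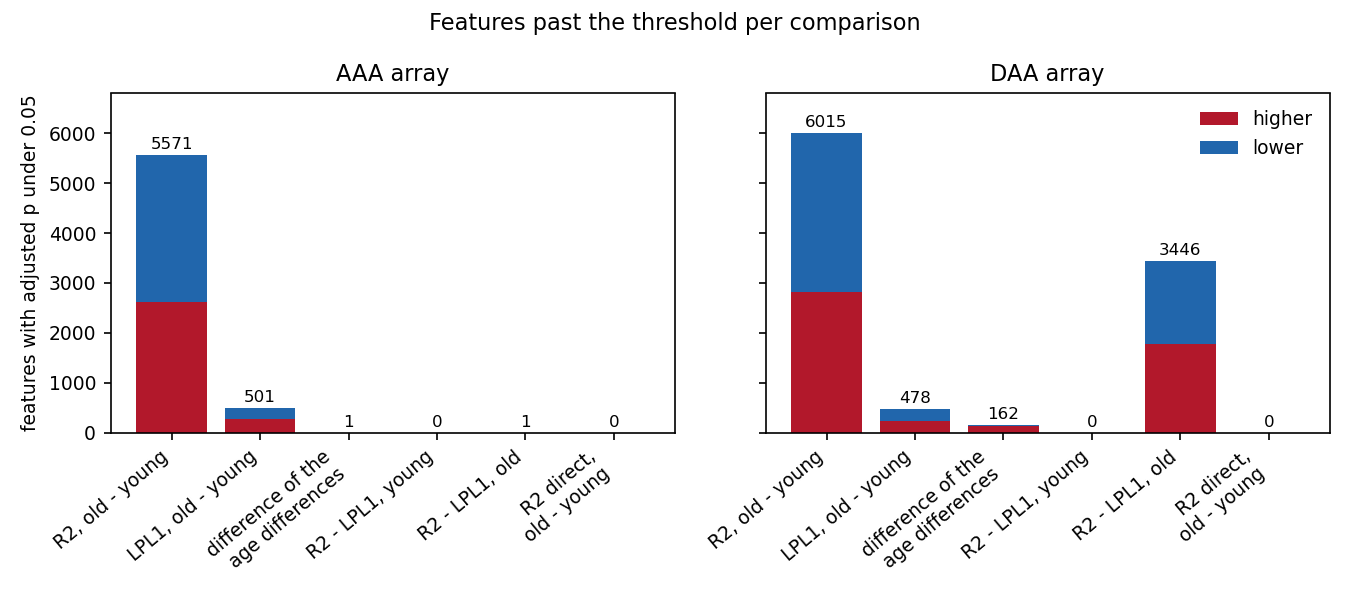
Number of features past limma's adjusted p of 0.05 (vertical axis, higher and lower stacked) for each comparison on AAA and DAA. In R2 5571 and 6015 features passed with age against 501 and 478 in LPL1, and no feature passed on the direct R2 arrays of either platform.

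Whether age acts differently on the neurons was tested by the interaction, the age difference in R2 minus that in LPL1. No named feature passed. EPS15R was nearest, at 2.30 ± 0.31 log2 (SE; adjusted p = 0.132). It stood at 4.90 ± 0.35 in old and 3.21 ± 0.22 in young R2, against 3.89 ± 0.22 in old and 4.51 ± 0.25 in young LPL1 (log2 neuron/CNS, SD, n = 3). A receptor-type guanylyl cyclase, a class of enzyme that makes cyclic GMP, had 1.63 ± 0.29 (0.313), beta tubulin feature 30346 -2.71 ± 0.54, insulin-like peptide precursor II -1.57 ± 0.37 and a GABA transporter -1.68 ± 0.42 (0.325 each). So the larger number of calls in R2 does not show, gene by gene, that R2 and LPL1 differ. With array weights the counts for age were 2511 in R2 and 3128 in LPL1 on AAA, and 18136 and 2251 on DAA. SPTR prohormone, for example, was -3.14 in R2 and -2.12 in LPL1, where its adjusted p was 0.055.

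By camera with a preset correlation the tubulin and microtubule list was lower in the R2 age difference (median -1.37 log2, adjusted p = 1.0e-05; 0 of 32 features over all, 16 adjusted over the list alone). Ribosomal proteins (0.55, adjusted p = 0.00528) and translation factors (0.18, 0.00193) were higher. Each of these directions is relative to the other named features. The adjusted p was 0.995 with an estimated correlation for all 3 lists. The median of the neuropeptide list, not past the test, turned from -0.52 to 0.19 with quantile normalization.

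A single AAA feature passed the interaction, 36848, at -3.65 ± 0.31 log2 (adjusted p = 0.00664), and is named only by a fruit fly clone. It was picked after its values were seen. On DAA 162 features passed, 133 higher and 29 lower, and with quantile normalization 355 passed, 250 higher and 105 lower. The largest were features 24244 (4.05 ± 0.56, 0.0304) and 28639 (3.83 ± 0.51) upward, and 9914 (-3.68 ± 0.64, 0.0425) and 28935 (-3.06 ± 0.52, 0.0413) downward. With replicate numbers as a block 1 DAA feature passed. The AAA count was 2 and 16 without young LPL1 replicates 1 and 2, and 5 and 3 without old R2 replicates 1 and 3. The DAA count was 17 and 1 without young LPL1 replicates 1 and 3, 0 without any 1 of the young R2 arrays, 43, 1 and 0 without old LPL1 replicates 1, 2 and 3, and 607, 1283 and 5 without old R2 replicates 1, 2 and 3. In simulations the AAA test recovered 5% of 2-fold and 55% of 4-fold interaction changes, and the DAA test 2% and 48%.

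**Figure D3:**
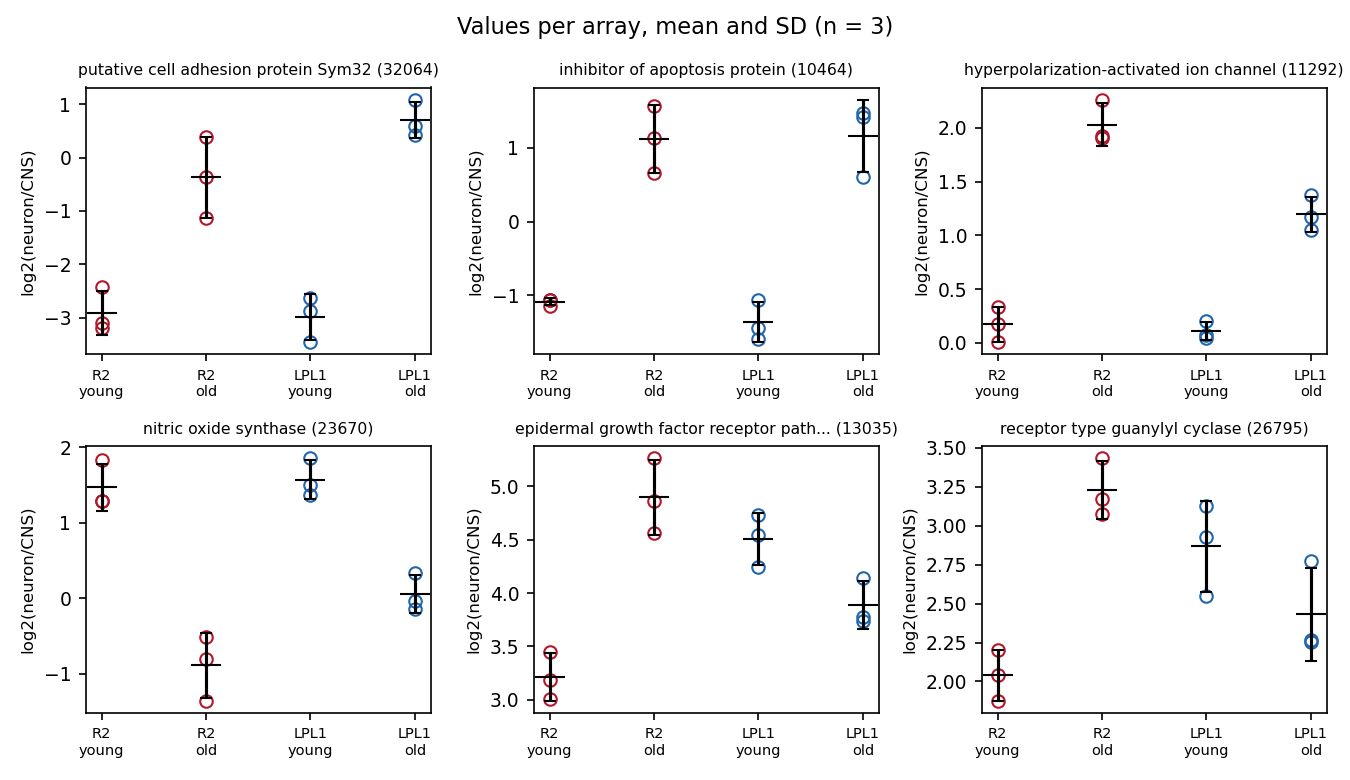
Log2(neuron/CNS) of 6 named AAA features (vertical axis) on each array of young and old R2 and LPL1, as points with mean and SD (n = 3). They are the features named among the largest changes of both neurons and those with the smallest interaction p, a choice made after the values were seen. Nitric oxide synthase goes from 1.47 to -0.89 in R2 and from 1.57 to 0.06 in LPL1, and receptor type guanylyl cyclase from 2.04 to 3.23 in R2 and from 2.87 to 2.43 in LPL1 (interaction not past the threshold).

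R2 was then compared with LPL1 at each age. Between young cells no named feature passed. EPS15R was -1.29 ± 0.22 log2 in R2 minus LPL1 (SE; adjusted p = 0.592), the guanylyl cyclase -0.83 ± 0.20, myosin essential light chain -0.85 ± 0.21, ZipA 0.74 ± 0.15 and matrilin, an extracellular matrix protein, 0.61 ± 0.16 (0.65 each). Between old cells the GABA transporter was -1.60 ± 0.30 (0.21), channel feature 11292 0.83 ± 0.16, beta tubulin feature 30346 -1.93 ± 0.38, an apical early endosomal glycoprotein 0.81 ± 0.17 and EPS15R 1.01 ± 0.22 (0.231 each). By camera with a preset correlation the tubulin list was lower in old R2 than in old LPL1 (median -1.11 log2, adjusted p = 1.1e-05; 16 of 32 adjusted over the list alone). In young cells ribosomal proteins (-0.30, 0.00786) and translation factors (-0.12, 0.00144) were lower in R2. Each of these lists was set against the other named features. The adjusted p was 0.995 with an estimated correlation for all 3.

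In young cells limma called 0 features on AAA (2711 at unadjusted p under 0.05) and 0 on DAA (1058), with 0 by the plain test on each feature's own spread as well. The AAA count was 2 without old R2 replicate 1, and the DAA count 1 without young LPL1 replicate 1 and 2 without young R2 replicate 3. In old cells 1 AAA feature passed (5856 at unadjusted p under 0.05), feature 16065, chosen after its values were seen, at 1.63 ± 0.23 in R2 and -0.86 ± 0.36 in LPL1 (log2 neuron/CNS, SD, n = 3; adjusted p = 0.0356). On DAA 3446 passed in old cells, 1781 higher and 1665 lower in R2, a balance that turned to 1645 and 1754 with quantile normalization and was 2027 and 1314 with each array centred. The largest of these were features 3198 (6.20 ± 1.42, 0.0286) and 41582 (5.47 ± 1.42) upward and 25220 (-3.45 ± 0.76, 0.0245) and 26275 (-3.40 ± 0.84) downward. Groups did not overlap for 29.5% of DAA and 16.6% of AAA features in old cells, and for 9.69% and 16.8% in young cells, where 0 passed (chance 10%).

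The number of calls between old cells depended on which arrays entered. Replicate numbers pair the old cells, and with them as a block 0 AAA and 2047 DAA features passed. The AAA count was 0 without young LPL1 replicate 2, young R2 replicates 2 or 3 or old LPL1 replicates 1 or 3, was 2 without young LPL1 replicate 3, old LPL1 replicate 2 or old R2 replicate 2, and was 3, 93 and 9 without young LPL1 replicate 1 and old R2 replicates 1 and 3. The DAA count was 2024 without young R2 replicate 2, 1766, 641 and 976 without old LPL1 replicates 1, 2 and 3, and 7341 and 992 without old R2 replicates 2 and 3. With only the 6 old arrays in the fit limma called 0 features on either platform.

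Both neurons together were compared with the CNS, which asks what these cells hold relative to nervous tissue as a whole. EPS15R was 4.13 ± 0.08 log2 higher in the neurons (SE, 12 arrays; adjusted p = 4.06e-11), the receptor-type guanylyl cyclase 2.64 ± 0.07 (4.09e-10) and myosin light chain kinase 2.27 ± 0.19 (1.59e-06). Neuropeptide precursors were far lower, with myomodulin at -6.53 ± 0.26 (7.81e-09), pedal peptide at -5.74 ± 0.16 (4.84e-10), PRQFVamide at -5.62 ± 0.27, a bradykinin-like peptide at -5.22 ± 0.11 and small cardioactive peptide B at -5.20 ± 0.16. The transcription factor aristaless-related homeobox 2 was at -6.39 ± 0.19. On AAA 29180 features passed, 14642 higher and 14538 lower in the neurons, and on DAA 27002, 14724 higher and 12278 lower, with features 10807 (4.69 ± 0.10) and 33129 (3.41 ± 0.14) highest and 10663 (-6.55 ± 0.40) and 6872 (-6.03 ± 0.20) lowest. Of features at least 2-fold apart, 1160 were higher and 3395 lower on AAA, and 1036 and 2415 on DAA. No dyes were swapped, so a probe's dye effect is part of each of these values. The reference is a common CNS RNA, of middle age per the authors' deposited tables, so neurons and CNS are not matched in age. The reference's own spread is left out. The standard errors and p-values here therefore measure only the spread among neuron arrays.

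None of 89 neuropeptide features was higher and 75 were lower in the neurons (76 adjusted over the list alone). Among 6 features of other transmitter phenotypes 0 were higher and 6 lower (6 adjusted over the list alone), among them sensorin A, a sensory neuron peptide (-4.64 ± 0.33), and tryptophan hydroxylase, which starts serotonin synthesis (-2.32 ± 0.19). Acetylcholine receptors had 0 higher and 7 lower of 11 (7 adjusted over the list alone), with a nicotinic alpha subunit at -1.71 ± 0.20. Other transmitter receptors had 5 higher and 11 lower of 22 (16 adjusted over the list alone), with GluR5 at 1.39 ± 0.17 and a 5-hydroxytryptamine receptor at -4.25 ± 0.14. Ion channels had 4 higher and 10 lower of 21 (14 adjusted over the list alone), with channel feature 11292 at 0.88 ± 0.06 and the calcium channel alpha 1F subunit at -2.35 ± 0.10. The growth factor list had 3 higher and 8 lower of 11 (11 adjusted over the list alone), with insulin precursor at -4.79 ± 0.11 and an insulin-like growth factor binding protein at -4.78 ± 0.16.

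The synaptic vesicle list had 7 higher and 4 lower of 27 (10 adjusted over the list alone), with beta-tubulin feature 30786 at 0.99 ± 0.16 and synapsin at -0.93 ± 0.17. Vesicle traffic had 1 higher and 14 lower of 16 (15 adjusted over the list alone), with prohormone convertase 2, a peptide-processing enzyme, at -1.94 ± 0.22. Glycolysis had 6 higher and 17 lower of 23 (23 adjusted over the list alone), with triosephosphate isomerase at 1.23 ± 0.09 and a hexokinase at -2.16 ± 0.20. Ribosomal proteins had 0 higher and 6 lower of 6 (6 adjusted over the list alone), with L5 at -1.33 ± 0.12, and the ubiquitin list 1 higher and 5 lower of 6 (6 adjusted over the list alone), with ubiquitin C at -1.82 ± 0.09. Chaperones had 5 higher and 9 lower of 17 (14 adjusted over the list alone), with HSP60 at -0.89 ± 0.14, and the tubulin list 5 higher and 13 lower of 32 (16 adjusted over the list alone), with kinesin heavy chain at 0.83 ± 0.18. Plasticity signalling had 8 higher and 7 lower of 22 (15 adjusted over the list alone), where the name calmodulin stood at 1.58 ± 0.16 on feature 39715 and at -3.75 ± 0.11 on feature 17448. In the glia and sheath list 2 were higher and 3 lower of 6 (5 adjusted over the list alone), with fibrillin-2 at -1.75 ± 0.12, and in the haemocyte list 0 were higher and 6 lower of 7 (6 adjusted over the list alone).

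**Figure D4:**
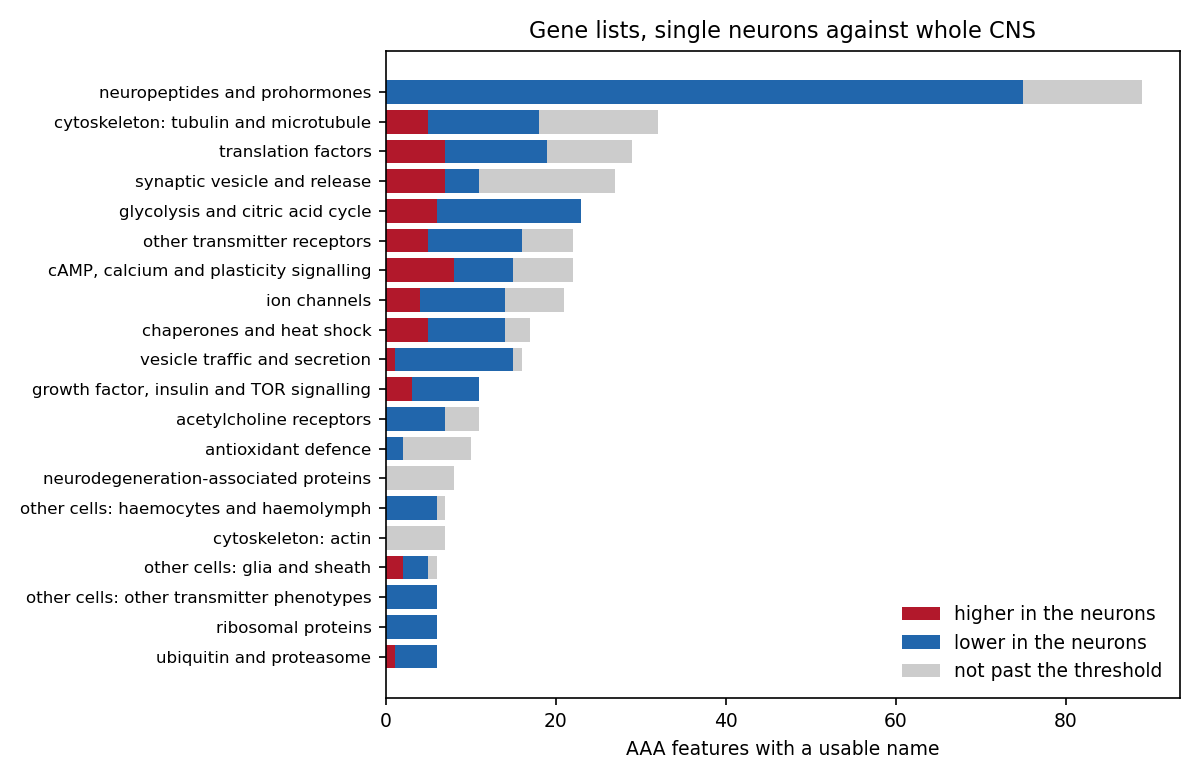
Number of named features per gene list (horizontal bars, stacked) that were higher, lower or not past limma's adjusted p of 0.05 in the neurons against the CNS on AAA. In the neuropeptide list 75 of 89 features were lower and 0 higher, and in the list of other transmitter phenotypes 6 of 6 were lower.

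Whole abdominal ganglia were compared directly, to set a mixed tissue beside the single cells. By the dyes in the labels, read in the orientation found for the reference arrays, soluble acetylcholine receptor, a name given to a secreted acetylcholine-binding protein, rose by 4.75 ± 0.28 log2 in old ganglia (SE, 3 arrays; adjusted p = 0.00738). EPS15R rose by 4.55 ± 0.08 (0.00656), the water channel AQP-h3 by 4.15 ± 0.18 (0.00674), the guanylyl cyclase by 2.50 ± 0.10 (0.00656) and a glutathione S-transferase by 1.97 ± 0.20 (0.00988). A calmodulin feature fell by 3.31 ± 0.12 (17448, 0.00656), WDFY3 by 3.24 ± 0.34 (0.0101), MIP-related peptide precursor by 2.69 ± 0.09 (0.00656), the kinase MNK2 by 2.65 ± 0.07, enterin precursor by 2.52 ± 0.21 (0.0081) and an FMRFamide precursor by 2.47 ± 0.17 (0.00738). The direction is likely but not settled. The 3 abdominal arrays as deposited correlated with the reference arrays at r = -0.516 to -0.352 across features, and no source states which channel is the numerator. With the sign turned every rise here is a fall and the reverse.

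By that direction 16751 features passed, 7930 higher and 8821 lower in old ganglia. With the sign turned 8821 were higher and 7930 lower. With eBayes trend and robust options 9111 were higher and 8981 lower. All 3 arrays had the same sign for 70.9% of features, where chance gives 25%. The count was 10577 without replicate 1, 4276 without replicate 2 and 0 without replicate 3, so none of the named calls held without replicate 3. With 1 array left out in turn, the difference ranged from 4.49 to 4.59 log2 for EPS15R, 2.41 to 2.58 for the guanylyl cyclase, -2.68 to -2.64 for MNK2 and -3.64 to -2.83 for WDFY3. By the plain test on each feature's own spread 33 features passed.

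Of 89 neuropeptide features 6 rose and 50 fell (63 adjusted over the list alone; with the sign turned, 50 rose and 6 fell). The list was lower than the other named features by camera with a preset correlation (median -0.62 log2, adjusted p = 0.000706, and 0.995 with an estimated correlation). Neuropeptide Y precursor rose by 1.56 ± 0.31 (0.0284) and pedal peptide by 1.40 ± 0.32 (0.0357). The growth factor list had 7 risers and 3 fallers of 11 (10 adjusted over the list alone, and turned 3 and 7). It was higher than the other named features by camera with a preset correlation (median 1.02, adjusted p = 0.0289, and 0.995 with an estimated correlation). Insulin precursor fell by 1.36 ± 0.14. Acetylcholine receptors had 4 risers, all of the soluble receptor name, and 3 fallers of 11 (7 adjusted over the list alone). Other transmitter receptors had 5 risers and 7 fallers of 22 (12 adjusted over the list alone), with GluR5 at 1.66 ± 0.11 and the 5-hydroxytryptamine receptor at -1.16 ± 0.08. Ion channels had 3 risers and 12 fallers of 21 (18 adjusted over the list alone), with sodium channel SCAP1 at -1.18 ± 0.14. Chaperones had 0 risers and 10 fallers of 17 (10 adjusted over the list alone), with protein disulfide-isomerase at -1.46 ± 0.08 and HSP60 at -1.43 ± 0.08. Vesicle traffic had 3 risers and 9 fallers of 16 (12 adjusted over the list alone), with a proprotein convertase 2 at -2.05 ± 0.12. The turned counts are those with risers and fallers exchanged.

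For features that moved in single cells, the comparison with the ganglion hangs on that direction. Nitric oxide synthase was 1.05 ± 0.07 there (0.00738), Sym32 -2.13 (0.01) and an inhibitor of apoptosis feature -1.49 ± 0.24 (8333, 0.019), each opposite in sign to its value in R2 by the direction of the dyes and alike in sign when it is turned. EPS15R (1.68 in R2, 4.55 in the ganglion) and the guanylyl cyclase (1.19 and 2.50) were alike in sign by the direction of the dyes. Of 2344 features called in both, 1434 had the same sign by that direction and the rest the opposite. Apart from these, antioxidant defence had 4 risers and 5 fallers of 10 (9 adjusted over the list alone), with ovoperoxidase at -1.87 ± 0.11, the ubiquitin list 1 and 4 of 6 (6 adjusted over the list alone), and ribosomal proteins 1 and 5 of 6 (6 adjusted over the list alone), with L5 at -1.41 ± 0.10 and L15 at 0.56 ± 0.12. Glycolysis had 1 riser and 6 fallers of 23 (7 adjusted over the list alone). Other transmitter phenotypes had 0 and 5 of 6 (5 adjusted over the list alone), with tryptophan hydroxylase at -1.41 ± 0.17.

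Direct arrays of old against young R2 gave 0 calls by limma on AAA (1903 at unadjusted p under 0.05) and 0 on DAA (2103), and 0 by the plain test as well. The named features nearest to passing were an inhibitor of apoptosis feature at 4.40 ± 0.37 log2 (8333, SE, 3 arrays), megalin, an endocytic receptor, at -3.66 ± 0.61, the neuron L11 neuropeptide precursor at 2.96 ± 0.50, a Frizzled receptor at 2.08 ± 0.39 and fatty acid binding protein 3 at 1.61 ± 0.28 (adjusted p = 0.98 each). All 3 arrays had the same sign for 24.4% of AAA and 25.8% of DAA features, where chance gives 25%, and replicate arrays correlated at -0.046 to 0.245 on AAA. In simulations the test recovered 0% of 2-fold and 0% of 4-fold changes on these arrays, so the count of 0 carries little information. The direction of these ratios, too, is likely but not stated.

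Age differences of R2 and LPL1 from the reference design correlated at r = 0.428 across features on AAA and 0.400 on DAA. Features are not independent replicates. Old R2 and old LPL1 arrays are likely paired by number, and this pairing with no age change at all would give r = 0.170 and 0.131. Of the covariance of 0.128 on either platform the pairing accounts for 0.0182 on AAA and 0.0150 on DAA. On AAA 381 features passed in both neurons, where independent lists would share 66.5, and 379 of them had the same sign, while on DAA 346 passed in both (68.4 by independence) and 340 had the same sign. These overlaps under independence leave the pairing out, and part of the excess may come from it. The R2 differences of the reference and direct arrays, which share old R2 material per the authors' methods text, correlated at 0.136 on AAA and 0.323 on DAA, and at -0.136 and -0.323 if the direct ratios run the other way. Without 1 array in turn the AAA value ranged from 0.0256 to 0.190. Shared old R2 material can by itself give a correlation between these differences. What it gives with no age change was not estimated for this pair. The R2 reference differences correlated with those of the abdominal ganglion at 0.157 by the likely direction (-0.157 with the sign turned), and at -0.0221 after quantile normalization.

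The authors' deposited tables from their analysis of variance list contigs over 2-fold apart. In the authors' deposited table of old against young R2, 720 AAA contigs were listed, 317 higher in old and 403 in young cells. The authors' deposited table for LPL1 lists 226, of which 149 were higher in old cells. For old LPL1 against old R2 the authors' deposited table lists 175, and for young cells 16. Of 183 names shared with the authors' deposited table for R2, 169 had the same sign here and 106 passed. Of 67 shared names in the authors' deposited table for LPL1, 63 had the same sign and 15 passed, and of 67 in the authors' deposited table for old LPL1 against old R2, 67 had the same sign and 0 passed (54 at unadjusted p under 0.05). The 3857 features of the authors' deposited SAM tables had the same sign here for 57.5% on the direct arrays (42.5% if these ratios run the other way), where 0 passed by limma (354 at unadjusted p under 0.05), and for 60.7% in the R2 reference design, where 599 passed.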

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

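All tests of explanations and all counts of other sample splits in this part were chosen after the results were seen, while the leave-one-out counts, the replicate block, array weights and the fits with fewer groups were planned.

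The age difference itself differed between R2 and LPL1 by the interaction test for 1 AAA feature and 162 DAA features. A limit at 2 (log10), possibly the mark of another processing, is on all 3 DAA old R2 arrays and no other DAA reference array. The few values at the limit cannot themselves make the 162 calls, but these calls cannot be told apart from such a processing. Of 100 splits drawn for each platform, 2 on AAA and 4 on DAA gave as many calls, the real ones included. These splits do not decide whether chance gives such counts, because splits that mix young and old arrays carry the age difference in their spread. The median standard error of the real split was 0.33 log2 on AAA and 0.34 on DAA, and that of splits mixing ages in both neurons 0.41 on either. The highest other splits gave 2913 and 5672 calls, many times the real counts, and point to a structure of the samples, here the labelled ages. By construction the first keeps the ages of 1 neuron whole, and the second, which turns those of 1 neuron whole, measures the sum of both age differences. Old R2 and old LPL1 are likely paired, and with the replicate block 1 DAA feature passed. That block also joins the young arrays, which share only a number. Leaving out single arrays moved the DAA count to 0 without any 1 young R2 array, to 17 and 1 without young LPL1 replicates 1 and 3, to 43, 1 and 0 without old LPL1 replicates 1, 2 and 3, and to 607, 1283 and 5 without old R2 replicates 1, 2 and 3.

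Splits of 3 against 3 arrays are only 10 and too few for a share under 0.05. For age in R2 the real split gave 5571 calls on AAA and 6015 on DAA and the highest other 1 and 0, so 1 split of each reached the real value. For age in LPL1 the real split gave 501 and 478 and the highest other 0 on both, again 1 split of each. Between young neurons the real split gave 0 and 0, the highest other 1 and 0, and all 10 splits reached the real value. Between old neurons 3 splits on AAA reached the real 1 (highest other 14), and 1 split on DAA the real 3446 (highest other 7). Of the 4 splits that part every pair of old cells, the highest other gave 0 on either platform, and of the 6 that keep a pair together the highest gave 14 and 7.

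A first pattern is that old R2 and old LPL1 differed at 3446 DAA features and 1 AAA feature. One array alone did not make the DAA count, whose lowest value with an array left out was 641 (without old LPL1 replicate 2), beside 1766 and 976 without old LPL1 replicates 1 and 3, 7341 and 992 without old R2 replicates 2 and 3, and 2024 without young R2 replicate 2. The estimate of spread shared with the young groups enters both platforms alike, with a median standard error of 0.242 log2 on DAA and 0.237 on AAA (overlapping ranges without 1 array). The differences themselves spread more on DAA (SD 0.63 against 0.46 log2). The DAA calls do depend on the young arrays in the fit, since no feature passed on either platform with only the old arrays. That fit also has fewer arrays to estimate the spread from, so the shared estimate cannot be told apart as a cause. A limit at 2 (log10), possibly from another processing, is on all 3 DAA old R2 arrays and no other DAA reference array. The few values at the limit cannot themselves make the 3446 calls, but these calls cannot be told apart from such a processing. On AAA the 1 old R2 array with the limit correlated with old LPL1 at 0.711 on average, between those without the limit (0.811 and 0.615). Age in R2 gave 7997 calls without that array (5571 with it). A difference between the old cells stays open.

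A second pattern is that features higher in the neurons than in the CNS were also higher in the old than in the young abdominal ganglion, by the direction of the dyes. A larger share of R2 in the old ganglion cannot be told apart, since the abdominal ratios as deposited correlated at -0.467 on average with young LPL1, which lies outside this ganglion, and at -0.390 with young R2, with overlapping ranges, and the young neurons themselves correlate at 0.804. A probe dye effect with that direction is excluded by the negative sign of the mean correlation with reference arrays, -0.423. Direct R2 arrays of the same dyes correlated with the reference arrays at 0.171, -0.0676 and -0.0787 (mean 0.00807), each smaller in size than the abdominal arrays (-0.439 to -0.410). These values argue only weakly against a dye effect with the ratios deposited the other way round. The direct R2 arrays correlate little even with each other (-0.046 to 0.245 on AAA), so they cannot exclude it. Age and the direction of the ratios stay open.

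A further pattern is the larger number of features changing with age in R2 than in LPL1, which array weights turn round on AAA (2511 in R2, 3128 in LPL1) but not on DAA (18136 and 2251). The limit at 2 (log10) is on all 3 DAA old R2 arrays and no other DAA reference array. The few values at the limit cannot themselves make the DAA excess. The limit may mark another processing of these arrays, from which that excess cannot be told apart. More RNA in old than in young samples cannot be told apart, since the old over young ratios, 4.50 in LPL1 and 4.01 in R2, have overlapping ranges (3.11 to 8 and 2.86 to 5.70). Sharing the estimate of spread between the neurons did not make the excess on AAA, as 2679 AAA features passed in R2 and 291 in LPL1 when each was fitted alone. Old and young arrays still share an estimate in those fits, while the AAA median SD was 0.33 log2 in old and 0.17 in young R2. Array weights turned the order on AAA, so the way spread is modelled is not excluded. Age acting on more transcripts in R2 stays open as a hypothesis, beside the likely pooling of young samples, which was not tested and which applies to both neurons.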

How the results depend on the processing

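The alternatives here were planned, except where said to have been added after seeing the data, and the cause of a change was not tested unless stated. A filter on dim probes was not run, as no intensities are held, so what signal over background limits is unknown. Median-centring kept all 7 DAA counts within 1.5 times. Keeping complete features only removed no tested feature and so tests nothing. Of the 15 counts per setting, 10 moved with array weights, 6 with the 2-fold minimum, 6 with the plain test on each feature's own spread, 4 with quantile normalization and 1 with trend and robust options. Of the named features over 5 alternatives, 304 values kept their direction and side of the threshold, 24 lost their call (18 of them with the plain test) and 2 gained one.

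Counts below are AAA, then DAA. With only the groups compared in the fit, fewer arrays estimate the spread, and age in R2 gave 2679 and 2410, age in LPL1 291 and 110, and old R2 minus old LPL1 0 and 0. With array weights age in R2 gave 2511 and 18136, age in LPL1 3128 and 2251, the interaction 3 and 3020, young R2 minus LPL1 55 and 1, and old R2 minus LPL1 0 and 12889. With at least 2-fold, a stricter demand by construction, age in R2 gave 3047 and 3160, neurons over CNS 4555 and 3451, the abdominal ganglion 3862 on AAA, and old R2 minus LPL1 1858 on DAA. With the plain test age in LPL1 gave 304 and 227, the interaction 0 and 90, old R2 minus LPL1 0 on AAA and the abdominal ganglion 33. With quantile normalization the interaction gave 4 and 355, and on AAA young R2 minus LPL1 gave 2 and old R2 minus LPL1 7. The AAA interaction gave 3 with values as deposited and 0 with trend and robust options.

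With the replicate block age in LPL1 gave 249 and 153, the DAA interaction 1, and old R2 minus LPL1 0 and 2047. The block moved no other count by over 1.5 times. Replicate numbers likely pair only the old cells. Young R2 and young LPL1 share only a number, with r of -0.130, -0.312 and -0.192 between same-numbered AAA arrays, and not every array correlated best with its own number. With the replicate block on the old arrays alone, added after seeing the data, old R2 minus LPL1 gave 0 and 0. Without the old R2 array limited at 2, also added, it gave 9 on AAA, and age in R2 7997.

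Of 140 gene list tests 10 passed. With an estimated correlation 0 passed, with fry 6, with quantile normalization 23, with all descriptive names whatever the E-value (added) 21, and with 1 value per name (added) 2, the tubulin list in the interaction and between old neurons (adjusted p = 0.0157 each, and 1.00 each with an estimated correlation). Correlations across features, over only those called in at least 1 of the comparisons, were 0.308 and 0.618 for R2 reference with R2 direct, 0.704 and 0.619 for R2 with LPL1, and 0.166 for R2 reference with the abdominal ganglion. The last, 0.157 over all features, turned to -0.0221 with quantile normalization. At unadjusted p under 0.05 the names shared with the authors' deposited tables that passed were 53 for LPL1, 54 for old LPL1 against old R2, 1 for young cells, and 354 and 1312 of the SAM features on direct and reference arrays.

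Leaving out 1 array in turn gave ranges of 1574 to 7997 and 2858 to 8168 for age in R2, 82 to 998 and 71 to 1283 for age in LPL1, 1 to 16 and 0 to 1283 for the interaction, 0 to 2 and 0 to 2 between young cells, 0 to 93 and 641 to 7341 between old cells, 27700 to 29776 and 25129 to 27853 for neurons over CNS, 0 to 0 on the direct R2 arrays of both platforms, and 0 to 10577 for the abdominal ganglion. The correlations ranged from 0.0256 to 0.190 and 0.233 to 0.392 (R2 reference with direct), 0.264 to 0.520 and 0.357 to 0.429 (R2 with LPL1), -0.158 to 0.0969 (R2 direct with abdominal, -0.0188 over all arrays) and 0.139 to 0.163 (R2 reference with abdominal).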

Other observations

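No test of an explanation stands in this part, and the values from the authors' tables follow lists and names chosen by the rules given. The authors' deposited tables, which average all features of a contig, add further values by transcript. In the authors' deposited table of old against young R2, soma ferritin, an iron store, was 4.66-fold and glutathione transferase 4.59-fold higher in old R2, pontin 6.17-fold and pedal peptide 6.14-fold. In the same authors' deposited table Elongation protein 3 was 13.7-fold, translation initiation factor 2 beta 5.90-fold and buccalin, a neuropeptide precursor, 4.47-fold higher in young R2. In the authors' deposited table for LPL1, MIP-related peptide was 6.50-fold, ferritin 5.24-fold, glutathione transferase 4.16-fold, the heat shock protein HSP70 2.60-fold and an amyloid precursor-like protein 3.10-fold higher in old cells, and beta-1 tubulin 4.85-fold higher in young cells. Tubulin and microtubule contigs were higher in old R2 in 1 case and in young R2 in 12 in the authors' deposited table (Fisher's exact test against the other contigs with a usable name, two-sided p = 0.00759, adjusted p = 0.0525 over 76 tests, so not past 0.05). Contigs are counted singly in these tests, here and below, though several can carry the same name and so are not independent.

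The authors label the CNS of these comparisons middle in age, so tissue and age differ together in them. Among named contigs in the authors' deposited table for the CNS against old R2, achatin-I was 66.4-fold, pedal peptide 65.6-fold, small cardioactive peptide B 52.8-fold and CP2 51.2-fold higher in the CNS. Of the neuropeptide list 36 contigs were higher in the CNS and 0 in old R2 (Fisher's exact test, adjusted p = 1.44e-05) in the authors' deposited table. Ribosomal proteins stood at 43 and 2 (adjusted p = 4.38e-05) and mitochondrial respiration at 31 and 1 (adjusted p = 0.000501) in the same authors' deposited table, with the larger number in the CNS. Mitochondrial respiration did not pass in the authors' deposited tables against old LPL1 (22 and 1, adjusted p = 0.0525), young R2 (9 and 1, 0.988) or young LPL1 (11 and 2, 0.988), nor did ribosomal proteins against young LPL1 (18 and 1, 0.191). For old LPL1 the authors' deposited table gave 34 and 1 for neuropeptides (adjusted p = 0.00229) and 42 and 0 for ribosomal proteins (adjusted p = 4.38e-05). In the authors' deposited table of old LPL1 against old R2, MIP-related peptide was 6.60-fold and FMRFamide 3.40-fold higher in LPL1, and PRQFVamide 5.36-fold and egg-laying hormone 2.88-fold higher in R2.

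The numerators in the authors' deposited SAM tables correlated with the R2 age difference of the reference arrays at r = 0.208 and with the direct R2 arrays at 0.147, -0.0370 and 0.117 across features, which are not independent replicates. Direct R2 replicates correlated with each other at -0.046 to 0.245 on AAA and -0.0094 to 0.263 on DAA, against 0.738 to 0.822 among the abdominal arrays.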
